A study of Mus musculus with 8 samples.

How the data were processed

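RNA was measured by sequencing in CD4+ T cells of B6 x 129 F1 mice, 12 weeks old, at day 30 after infection with Salmonella enterica. Cells that bound the LpdAp:I-Ab tetramer were sorted from spleen and lymph nodes as CX3CR1+ CXCR3- or CXCR3+ CX3CR1- cells. Per the labels, RNA was extracted with a Qiagen RNeasy Plus micro kit and libraries were made with the Takara Pico Mammalian kit with removal of ribosomal RNA. The values deposited by the authors are raw read counts per gene symbol in 1 table of 24420 genes and 8 libraries, not normalised. The labels name FastQC, HISAT2 2.1.0, Subread, edgeR and the mm10 genome without saying what each step did. The annotation, the strand setting and the treatment of reads that match more than 1 gene are not given in the sources used here. Values of genes with near-identical copies, such as the Klra genes, the histone genes, Ly6c2 and the glycolysis genes Gapdh, Pgam1 and Tpi1, and of genes that overlap on opposite strands are therefore uncertain in their assignment.

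All 8 libraries were used, 4 per population, and no column was set aside. A total of 27 symbols had been turned into dates and were not matched to a gene. Coordinates came from GENCODE M21 on GRCm38 (mm10), and 23975 symbols (98.2%) matched 1 annotated gene, 669 of them through an older symbol. The design text speaks of 4 mice, but the labels do not pair the libraries by mouse. Of the numbers in the titles, 1 and 4 occur in both populations, while the title P8 occurs in the CX3CR1+ population only. The remaining CX3CR1+ titles hold the tag P11 and all CXCR3+ titles the tag P9, so these tags follow the populations too.

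Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with filterByExpr by group (minimum count 10, minimum total 15), which left 11028, and scaled by TMM. Each gene was tested with the quasi-likelihood F test of edgeR, CX3CR1+ minus CXCR3+, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change was its absolute value divided by the square root of F. CPM values are TMM-scaled, and plots on a log scale add 0.1 to CPM. Where a group had 0 counts of a gene, the fold was a lower bound taken at 3 counts over the group, and with 1 to 3 counts the ratio was given with its exact conditional 95% interval.

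A set of 29 gene lists was fixed before the data were examined, as were the comparison, most tests and alternatives, and the rule for named genes. The rule took Cxcr3 and Cx3cr1, a fixed panel of Tbx21, Ifng, Klrg1, Zeb2, S1pr5, Gzmb, Cxcr6, Tcf7, Ccr7, Il7r, Bcl6 and Cxcr5, and the 6 largest log2 fold changes in each direction among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups. It also took, for each list, up to 3 tested members with the smallest adjusted p among those past 0.05, which gave 88 genes in all. The lists cover helper lineages, cytotoxicity, memory, inhibitory and costimulatory receptors, trafficking and residency, immediate early, interferon, stress and p53 genes, cell cycle and metabolism, and markers of other cell types that a sort could carry along. The 22 lists with at least 5 tested members were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation, with fry, and with an exact permutation of the list mean. The exact permutations of list means, and those of list sums, were not among the tests fixed before the data were examined. Member counts were taken from the adjusted p over all genes and adjusted over the list alone. The lists share members, for example Icos in the follicular helper and costimulation lists and Klrg1 in the cytotoxic and inhibitory receptor lists.

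Library properties were compared by exact two-sided permutation of 4 against 4 libraries, with 70 assignments and a smallest p of 0.0286. The shares of Rn45s and Malat1 were not among the properties fixed before the data were examined. The shares of mitochondrial and haemoglobin genes were, but they were not tested. Pairs of libraries within a population were checked for repeated deposits by the chi-square of their counts per degree of freedom over genes with at least 10 reads, which ran from 15.1 to 117, so that no pair differed by counting error alone. The steps were tested on simulated data made from these counts, with 10770 genes of which 200 were changed. There, 39% of genes changed 2-fold and 78% of genes changed 4-fold were called, 5.65% of calls were of unchanged genes, a list raised on purpose had adjusted p = 3.42e-37 and an unchanged list 0.737. The simulated genes varied independently, while members of real lists moved together, with an estimated correlation of 0.75 for cell cycle and 0.77 for macrophage genes. In the real data 25.2% of genes were called. The simulation therefore does not test the preset correlation of camera or the share of false calls under these conditions. The common biological coefficient of variation was 0.310. A total of 3 counts, the limit that a count of 0 allows, corresponds to 0.238 to 0.383 CPM per library.

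Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no count filter, a filter at CPM above 1 in 4 libraries, DESeq2, limma-voom with and without quality weights, robust dispersion, leaving out each library, a replicate block over the title numbers (as a fixed term, as a random effect and on the libraries numbered 1 and 4 alone), and a term for or removal of the libraries titled P8. The others were removal of 60 antigen receptor segments, haemoglobins, Xist and Y-linked genes, a test against a fold of 1.5 and a threshold of 0.01. As a fixed term, the replicate block took the contrast from the libraries numbered 1 and 4 alone, since the other numbers occur in 1 population only. The count filter was applied anew in each alternative, so that with fewer libraries a list could hold more tested members. Chosen after seeing the data were removal of or a term for the 2 libraries with over 100 reads of 4 Y-linked genes, removal of Rn45s, removal of the trend of each library with gene length or GC content (loess span 0.4), and the libraries numbered 1 and 4 without a block. The gene families of the closing part were also chosen after seeing the data. Values of 4 libraries in a group were examined for a library that stood apart by Dixon's criterion at its 95% critical value.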

Results

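RNA sequencing was carried out on 2 populations of CD4+ T cells that recognised the same peptide of Salmonella enterica, taken from the spleen and lymph nodes of infected mice at day 30. The cells bound the LpdAp:I-Ab tetramer, a reagent that marks T cells by the antigen their receptor recognises, and were sorted by surface CX3CR1 and CXCR3, a pair of chemokine receptors. There were 4 libraries of CX3CR1+ CXCR3- cells, titled 1P11, 4P11, P8-2 and P8-4 and named here replicates 1, 4, P8-2 and P8-4. The 4 libraries of CXCR3+ CX3CR1- cells were titled 1P9, 4P9, 5P9 and 6P9 and are named replicates 1, 4, 5 and 6. Total counts ran from 8419493 to 11215633 reads per library, and between 12634 and 17449 genes had at least 1 read. Values are read counts scaled to library size (CPM), given as mean ± SD with n = 4 per group, and every log2 fold change is CX3CR1+ minus CXCR3+. The labels do not tie each library to its own mouse, so the p-values measure the spread between libraries, and the intervals and floors cover counting error only.

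The comparison asks how the antigen-specific cells that carry CX3CR1 differ in their transcripts from those that carry CXCR3. Both receptors used for sorting differed in the direction of the sort. Cx3cr1, the fractalkine receptor (chromosome 9, 119901616 to 120069879, GRCm38), was 106-fold higher in CX3CR1+ cells at 572 ± 141 CPM against 5.28 ± 3.90 CPM, a log2 fold change of 6.73 (SE 0.519, adjusted p = 6.09e-05, edgeR). Cxcr3, the receptor for interferon-induced chemokines (chromosome X, 101731535 to 101734269), stood at 5.13 ± 2.53 CPM in CX3CR1+ cells and 91.5 ± 20.6 CPM in CXCR3+ cells, a log2 fold change of -4.13 (SE 0.330, adjusted p = 6.68e-05). No library of either group overlapped the other group for either gene. Cx3cr1 ran from 431 to 734 CPM in CX3CR1+ libraries and from 0.957 to 9.10 CPM in CXCR3+ libraries.

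**Figure D1:**
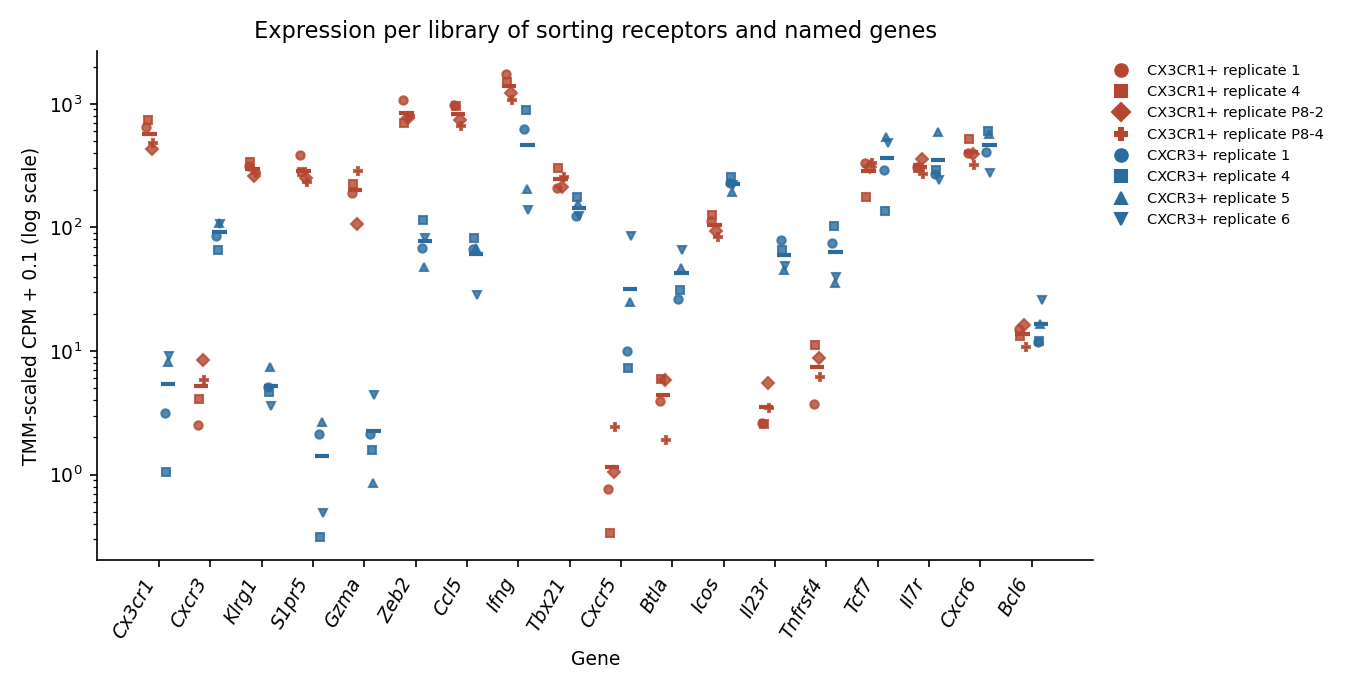
CPM plus 0.1 on a log scale in each of the 8 libraries for 18 named genes, with points for libraries and lines for group means (n = 4 per group). Cx3cr1 lies between 431 and 734 CPM in the CX3CR1+ libraries and at 9.10 CPM or below in the CXCR3+ libraries, and Cxcr3 lies the other way.

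Much of the measured transcriptome differed between the populations. Of 11028 genes tested, 1378 were higher and 1399 lower in CX3CR1+ cells at adjusted p under 0.05 (25.2%), and 501 and 643 of these differed by at least 2-fold. Among called genes with a mean log2 CPM of at least 3 and no overlap between the groups, the 6 largest differences upward included S1pr5, a sphingosine-1-phosphate receptor that guides exit from tissues, Gzma, a granzyme of cytotoxic granules, and Klrg1, an inhibitory receptor of terminally differentiated effector cells. The 6 largest downward included Rgs10, a regulator of G-protein signalling, St6gal1, a sialyltransferase, and Cxcr5, the chemokine receptor of B cell follicles. S1pr5 (chromosome 9, 21242912 to 21248443) reached 288 ± 69.9 CPM against 1.30 ± 1.18 CPM, a log2 fold change of 7.78 (SE 0.479, adjusted p = 1.27e-05). For Gzma (chromosome 13, 113093825 to 113100981) the values were 202 ± 74.9 CPM against 2.15 ± 1.53 CPM and a log2 fold change of 6.54 (SE 0.464, adjusted p = 3.83e-05). Klrg1 (chromosome 6, 122270596 to 122282882) had the smallest adjusted p of the named genes, 2.30e-07, with 297 ± 34.9 CPM against 5.10 ± 1.61 CPM.

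Completing the 6 largest upward differences beside Cx3cr1 were As3mt, an arsenite methyltransferase (chromosome 19, 46707458 to 46741099), with a log2 fold change of 5.61 (SE 0.288), and Notch3, a Notch receptor (chromosome 17, 32120820 to 32166852), with 5.42 (SE 0.442). In the other direction Rgs10 (chromosome 7, 128373621 to 128418758) stood at 0.207 ± 0.239 CPM against 19.1 ± 4.82 CPM, a log2 fold change of -6.29 (SE 0.592, adjusted p = 0.000172). St6gal1 (chromosome 16, 23224740 to 23360350) had a log2 fold change of -6.23 (SE 0.960, adjusted p = 0.00151), and Aff3, a nuclear protein of lymphoid cells (chromosome 1, 38177326 to 38664955), -5.21 (SE 0.785, adjusted p = 0.00142). Cxcr5 (chromosome 9, 44511787 to 44561877) had -4.87 (SE 0.874, adjusted p = 0.00312), at 1.04 ± 0.907 CPM against 31.9 ± 36.7 CPM. Cxcr5, Aff3 and St6gal1 were highest in CXCR3+ replicate 6, the library that also carried macrophage, class II and Cd22 transcripts, with 85.7 CPM of Cxcr5 (at least 7.23 in the others), 59.5 CPM of Aff3 (others 8.51 to 17.0) and 34.5 CPM of St6gal1 (3.32 to 21.0). Without it the log2 fold changes of the 3 genes were -3.69, -4.31 and -5.59 (adjusted p = 0.00378, 0.00224 and 0.00309). Hist1h3h, a histone H3 gene (chromosome 13, 21717659 to 21718069), had -4.74 (SE 1.04, adjusted p = 0.00794), and Atp8a2, a phospholipid flippase (chromosome 14, 59638540 to 60197179), -4.52 (SE 0.725, adjusted p = 0.00179). The groups did not overlap for 1627 higher and 1441 lower genes, 27.8% of those tested, where chance gives 2.86%, and among called genes for 1260 higher and 1177 lower. Without CXCR3 replicate 4 the value of Hist1h3h was -2.81 (adjusted p = 0.0144), and limma-voom ended the calls of Cxcr5 (adjusted p = 0.102), Aff3 (0.0602), St6gal1 (0.0607) and Hist1h3h (0.198).

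**Figure D2:**
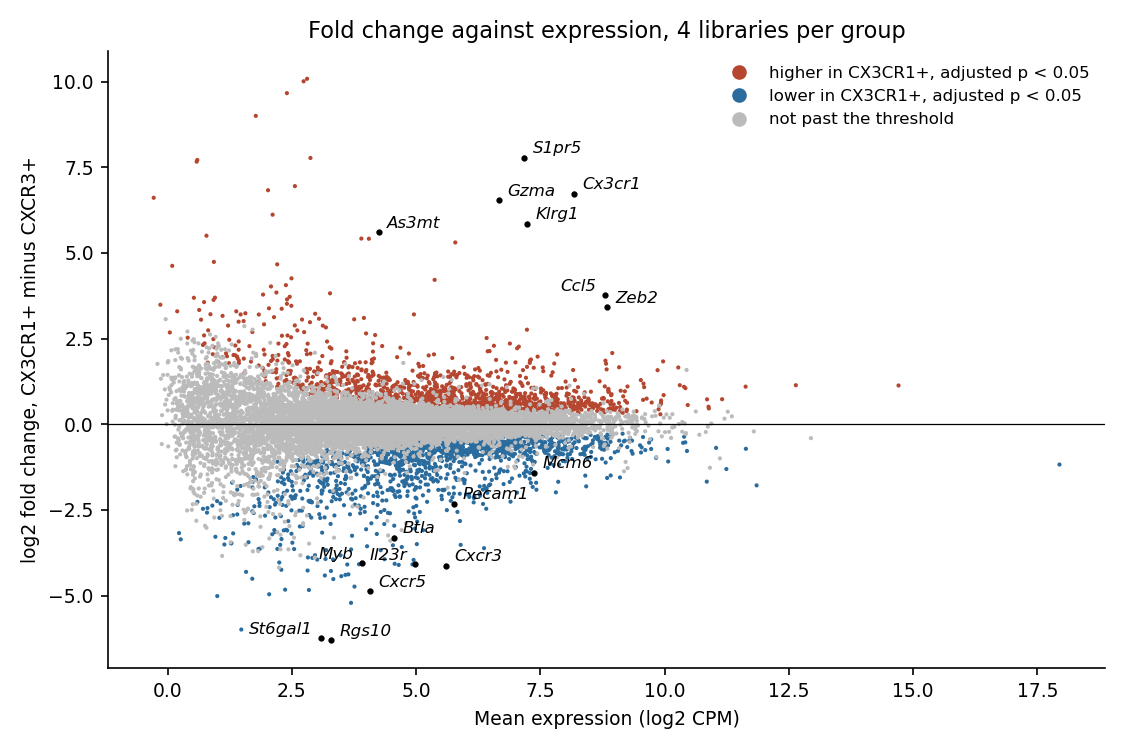
Log2 fold change of each of the 11028 tested genes (CX3CR1+ minus CXCR3+, vertical axis) against its mean log2 CPM (horizontal axis), with genes past adjusted p 0.05 coloured by direction. The 1378 higher and 1399 lower genes spread on both sides of 0, with S1pr5 at 7.78 and Rgs10 at -6.29.

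Genes of cytotoxicity and terminal effector differentiation were higher in part in CX3CR1+ cells. In the list of cytotoxic and terminal effector genes, which counts Cx3cr1 among its members, 13 of 26 tested members were higher, 0 were lower and 13 did not pass, and 13 were higher and 1 lower when adjusted over the list alone. The list median was 1.02 (log2), or 1.56 without CXCR3 replicate 6, and its members together summed to 3795 ± 444 CPM against 1304 ± 150 CPM. Cx3cr1, on which the cells were sorted, was 1 of the 13 and held 572 CPM of the first sum and 5.28 CPM of the second. The counts, the sums and the test of this list were not repeated without Cx3cr1. Beside Klrg1, Gzma and S1pr5, Zeb2, a transcription factor of terminal effector cells, was higher at a log2 fold change of 3.43 (SE 0.257, adjusted p = 5.04e-05). Gzmb, the gene of granzyme B, stood at 48.7 ± 35.4 CPM against 19.9 ± 16.7 CPM and did not pass (log2 fold change 1.29, adjusted p = 0.114), although it did without CXCR3 replicate 4 (2.06, adjusted p = 0.0153). The list passed the camera test at adjusted p = 5.04e-05, against adjusted p = 0.192 with an estimated correlation.

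T helper 1 genes were also higher in part. Of 22 tested members, 10 were higher, 0 lower and 12 not past the threshold, with the same 10 and 0 adjusted over the list alone, and the list median was 0.35, or 0.20 without CXCR3 replicate 6. Tbx21, the transcription factor T-bet that directs the T helper 1 programme, was higher by a log2 fold change of 0.76 (SE 0.161, adjusted p = 0.00684). Ccl5, a chemokine of effector T cells, rose more, by 3.77 (SE 0.296, adjusted p = 6.47e-05), and Il18rap, a chain of the interleukin 18 receptor, by 1.66 (SE 0.131, adjusted p = 6.47e-05). Ifng, the gene of interferon gamma, was at 1390 ± 297 CPM against 466 ± 359 CPM, a log2 fold change of 1.58 (SE 0.488, adjusted p = 0.0364). Within the CXCR3+ group Ifng stood at 625 and 897 CPM in replicates 1 and 4 and at 203 and 138 CPM in replicates 5 and 6, and without the latter pair its log2 fold change was 0.83 (adjusted p = 0.0246). Its call was lost without CX3CR1 replicate 1 (adjusted p = 0.0953), 4 (0.0666), P8-2 (0.0710) or P8-4 (0.0513), without CXCR3 replicate 1 (0.0508) or 5 (0.0749), with robust dispersion estimates (0.107) and with a term for the libraries titled P8 (0.0579) or without them (0.103). The list passed camera at adjusted p = 0.0414, with adjusted p = 0.671 with an estimated correlation. It did not pass without CX3CR1 replicate 4 (0.125), without CXCR3 replicate 6 (0.104), without CXCR3 replicates 5 and 6 together (0.0847) or with a term for their Y-linked reads (0.117), nor with a replicate block on all libraries (0.118) or on those numbered 1 and 4 (0.109).

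Natural killer cell receptor genes were present among the higher genes. In the list of natural killer cell markers 3 of 7 tested members were higher and 0 lower, the same 3 and 0 adjusted over the list alone. The median of 0.75 over 7 members was unstable, at 0.32 without CX3CR1 replicate P8-4, also over 7. It was 3.97 without CX3CR1 replicate 4, and 3.62, 3.50, 3.91 and 3.90 without CXCR3 replicates 1, 4, 5 and 6. In each of these last settings 8 members passed the count filter and 4 were higher, so the larger medians are of a changed list. With all libraries the 3 higher genes were Klri2, Klra3 and Klra9, lectin-like receptors found on natural killer cells. Klri2 had 576 counts over the CX3CR1+ libraries and 2 over the CXCR3+ libraries, a ratio of 261 (95% exact conditional interval 72.1 to 2160), and Klra3 had 487 and 3, a ratio of 147 (50.1 to 717). Klra9 had 105 and 0 counts and was at least 31.8-fold higher, taking 3 counts over the group as the floor. The Klra family holds near-identical copies, and how reads shared between them were counted is not given in the sources used here. The list did not pass camera (adjusted p = 0.0661) but did without CX3CR1 replicate 1 (0.0384), 4 (0.00787) or P8-4 (0.0459), or without CXCR3 replicate 1 (0.0200), 4 (0.0192), 5 (0.0329) or 6 (0.0108), without both libraries titled P8 (0.0470) or without CXCR3 replicates 5 and 6 together (0.0218).

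Follicular helper genes were lower in CX3CR1+ cells almost without exception. Of 18 tested members 16 were lower, 0 higher and 2 not past the threshold, again 16 and 0 adjusted over the list alone, with a median of -1.89 and sums of 614 ± 76.0 CPM against 1331 ± 210 CPM. Beside Cxcr5, these included Btla, an inhibitory receptor of the immunoglobulin family, at -3.31 (SE 0.397, adjusted p = 0.000611), Tbc1d4, a Rab GTPase-activating protein, at -3.05 (SE 0.374, adjusted p = 0.000693), and Icos, a costimulatory receptor of follicular helper cells, at -1.11 (SE 0.147, adjusted p = 0.000855). Bcl6, the transcription factor of the follicular helper programme, was 13.7 CPM against 16.5 CPM and did not pass (log2 fold change -0.27, adjusted p = 0.507). The list passed camera at adjusted p = 5.01e-09, against adjusted p = 0.192 with an estimated correlation, and 9 members were lower without the libraries titled P8.

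Among genes of lymphoid homing and central memory, 3 of 20 were higher, 6 lower and 11 not past the threshold, with the same 3 and 6 adjusted over the list alone and a median of -0.21. Klf2, a transcription factor of quiescent, circulating T cells, was higher by 2.08 (SE 0.234, adjusted p = 0.000471). Myb, a transcription factor linked to self-renewal, was lower at -4.04 (SE 0.606, adjusted p = 0.00139), and Ltb, the gene of lymphotoxin beta, at -1.34 (SE 0.205, adjusted p = 0.00146). Tcf7, a transcription factor of memory precursors, had a log2 fold change of -0.34 (adjusted p = 0.527) and Il7r, the interleukin 7 receptor, -0.17 (adjusted p = 0.654). Ccr7, the lymph node homing receptor, was below the count filter and not tested. It had 0 counts over the CX3CR1+ libraries and 130 over the CXCR3+ libraries, at least 47.7-fold lower in CX3CR1+ cells with the floor of 3 counts. Of these, 58 lay in each of CXCR3+ replicates 5 and 6, the libraries with Y-linked reads, and 12 and 2 in replicates 1 and 4, so the floor rests mainly on that pair. The list did not pass camera (adjusted p = 0.365), its median was -0.32 without CX3CR1 replicate 1 and -0.12 without CXCR3 replicate 5, and its sum was 3235 ± 286 CPM against 2837 ± 448 CPM (exact permutation p = 0.229).

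Genes of other helper lineages were lower in part. Of 13 regulatory T cell genes 1 was higher and 5 lower (1 and 5 adjusted over the list alone, median -1.31, camera adjusted p = 0.0874). The lower genes included Tnfrsf4, the costimulatory receptor OX40, at -3.09 (SE 0.412, adjusted p = 0.000855), and Tigit, an inhibitory receptor, at -1.76 (SE 0.385, adjusted p = 0.00786), while Socs2, a suppressor of cytokine signalling, was higher at 1.38. Of 9 T helper 17 genes 1 was higher and 3 lower (1 and 3 adjusted over the list alone, median -0.44, camera adjusted p = 0.0946). The sum of the list was higher, at 1040 ± 134 CPM against 781 ± 79.9 CPM (exact permutation p = 0.0286, 0.0638 after adjustment). Il23r, the interleukin 23 receptor, was lower at -4.09 (SE 0.297, adjusted p = 4.15e-05), and Il1r1, an interleukin 1 receptor, at -4.09 (SE 0.905, adjusted p = 0.00833), or at -6.83 without CX3CR1 replicate P8-4. Rora, a nuclear receptor shared with innate lymphoid cells, was higher at 0.71 (SE 0.137, adjusted p = 0.00435). Of 4 tested T helper 2 genes, too few for the list test, 2 were lower, Il1rl1, the interleukin 33 receptor, at -1.44 and Ccr4, a chemokine receptor, at -4.51. The regulatory list passed without CX3CR1 replicate 4 (adjusted p = 0.0300) or P8-2 (0.0316) or CXCR3 replicate 5 (0.0340) and had 3 members lower without CXCR3 replicate 4. It also passed with a replicate block on all libraries (0.0107) or on those numbered 1 and 4 (0.00633), and on the latter without a block (0.0433). In each of these settings the contrast comes from the libraries numbered 1 and 4 alone, so they are not separate support. The T helper 17 list passed without CXCR3 replicate 1 (0.0341, median -0.66) or 4 (0.0441, median -0.80), without CX3CR1 replicate P8-2 (0.0316, median -0.86) or P8-4 (0.0364, median -1.14), without both libraries titled P8 (0.00290, median -4.13) or with a term for them (0.0119). Without CXCR3 replicate 4 or CX3CR1 replicate P8-2 or P8-4 the T helper 17 list held 10 tested members, and without both libraries titled P8 11. These medians are therefore of a changed list. Its median was -0.25, over 9 members, without CXCR3 replicate 5. It also passed with the block on all libraries (0.0225) or on those numbered 1 and 4 (0.0185), and on the latter without a block (0.0156), again from the same libraries.

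Costimulatory and cytokine signalling genes were lower in part, and inhibitory receptors went both ways. Of 22 costimulation and cytokine signalling genes 1 was higher and 8 lower, also 1 and 8 adjusted over the list alone (median -0.31, camera adjusted p = 0.0126, adjusted p = 0.593 with an estimated correlation). Il10ra, a chain of the interleukin 10 receptor, was the member that was higher, at 1.64 (SE 0.270, adjusted p = 0.00210), and Tnfrsf4 and Icos were among the 8. The list sum was 3098 ± 290 CPM against 3540 ± 569 CPM and did not pass (exact permutation p = 0.229, 0.302 after adjustment). Of 13 inhibitory receptor genes 2 were higher and 6 lower (2 and 8 adjusted over the list alone, median -1.20, camera adjusted p = 0.199). The 2 higher were Klrg1 and Lair1, a collagen receptor, at 1.47 (SE 0.176, adjusted p = 0.000611), and the list sum was 701 ± 139 CPM against 463 ± 197 CPM (exact permutation p = 0.114), the opposite sign to its median. The costimulation median was -0.51 without CX3CR1 replicate 4. Without CXCR3 replicate 4, 5 costimulation members were lower and 4 inhibitory receptors higher, and without CXCR3 replicate 5, 2 costimulation members were higher. Inhibitory receptors numbered 3 lower without CX3CR1 replicate 1, P8-2 or P8-4.

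Receptors for movement through blood and tissue were mixed. Of 25 trafficking receptor genes 6 were higher, 4 lower and 15 not past the threshold (7 and 4 adjusted over the list alone, median 0.24, camera adjusted p = 0.110). The higher genes included Itga4, the alpha 4 integrin, at 1.14 (SE 0.189, adjusted p = 0.00218) beside S1pr5, and the lower genes included Cxcr5 and Ccr4. Of 13 tissue residency genes 2 were higher and 2 lower (2 and 3 adjusted over the list alone, median -0.18, camera adjusted p = 0.683). Rgs2, a regulator of G-protein signalling, was higher at 1.58 (SE 0.282, adjusted p = 0.00303) and Inpp4b, a phosphoinositide phosphatase, lower at -1.43 (SE 0.231, adjusted p = 0.00189). Cxcr6, a receptor of tissue-lodged T cells, stood at 410 CPM against 463 CPM (log2 fold change -0.18, adjusted p = 0.617). Without CXCR3 replicate 5 the trafficking list passed (adjusted p = 0.0353), with 11 higher and 2 lower, as it did with a replicate block on all libraries (0.0354) or on those numbered 1 and 4 (0.0295), and on the latter without a block (0.0433). The settings with and without a block all take the contrast from the libraries numbered 1 and 4, so they are not separate support for the trafficking list. That list did not pass with any other single library left out, and its median was 0.06 (adjusted p = 0.413) without CX3CR1 replicate 4, 0.12 without CX3CR1 replicate 1 and 0.43 without CXCR3 replicate 5. The residency median was -0.50 without CX3CR1 replicate 4 or CXCR3 replicate 5, -0.03 without CXCR3 replicate 4 and -0.10 without CX3CR1 replicate P8-4. Residency members numbered 1 higher without CX3CR1 replicate 4 or P8-2 or CXCR3 replicate 1 or 4, and 1 lower without CX3CR1 replicate 1, P8-2 or P8-4 or CXCR3 replicate 4 or 6.

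Cell cycle genes were lower in CX3CR1+ cells nearly as a whole. Of 28 members 26 were lower, 0 higher and 2 not past the threshold, and 28 were lower and 0 higher adjusted over the list alone, with a median of -1.84. Together they summed to 2244 ± 914 CPM against 6763 ± 1735 CPM. Mcm6, Mcm7 and Mcm5, subunits of the helicase that opens DNA for replication, were lower at -1.41 (SE 0.140, adjusted p = 0.000253), -1.63 (SE 0.180, adjusted p = 0.000428) and -1.87 (SE 0.214, adjusted p = 0.000493). Camera gave adjusted p = 1.67e-13, against adjusted p = 0.460 with an estimated correlation, and between 22 and 27 members were lower with any 1 library left out.

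Genes of energy metabolism were also lower in part. Of 19 glycolysis genes 11 were lower and 0 higher (12 and 0 adjusted over the list alone, median -1.08, camera adjusted p = 2.43e-05, adjusted p = 0.562 with an estimated correlation). Ldha, lactate dehydrogenase A, was lower at -1.08 (SE 0.185, adjusted p = 0.00245), Slc16a1, a lactate transporter, at -1.17 (SE 0.149, adjusted p = 0.000743), and Pdk1, a kinase that restrains pyruvate dehydrogenase, at -1.72 (SE 0.313, adjusted p = 0.00334). Of 29 oxidative phosphorylation genes 9 were lower and 0 higher (12 and 0 adjusted over the list alone, median -0.43, camera adjusted p = 5.04e-05, adjusted p = 0.460 with an estimated correlation). Among them were the ATP synthase genes Atp5b at -0.71 (SE 0.118, adjusted p = 0.00218) and Atp5a1 at -0.73 (SE 0.127, adjusted p = 0.00273), and Ndufa4 at -1.33 (SE 0.272, adjusted p = 0.00581). Of 18 cholesterol synthesis genes 1 was higher and 2 lower (1 and 1 adjusted over the list alone, median -0.20, camera adjusted p = 0.636). Mvd was the higher gene at 0.92, and Fdps was lower at 9.31 CPM against 18.7 CPM (adjusted p = 0.0106), both enzymes of the mevalonate pathway. Oxidative phosphorylation members numbered 4 lower without CX3CR1 replicate 1, 3 without P8-2 and 5 without CXCR3 replicate 1, and 6 with the trend with gene length removed. Without the libraries titled P8 there were 3, with 4 of glycolysis. Cholesterol synthesis members numbered 4 lower without CXCR3 replicate 4, 2 higher without CXCR3 replicate 5, and 1 lower without CX3CR1 replicate 1, 4 or P8-2 or CXCR3 replicate 1, 5 or 6. The cholesterol synthesis median was -0.08 without CXCR3 replicate 5 and -0.32 without CXCR3 replicate 4.

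**Figure D3:**
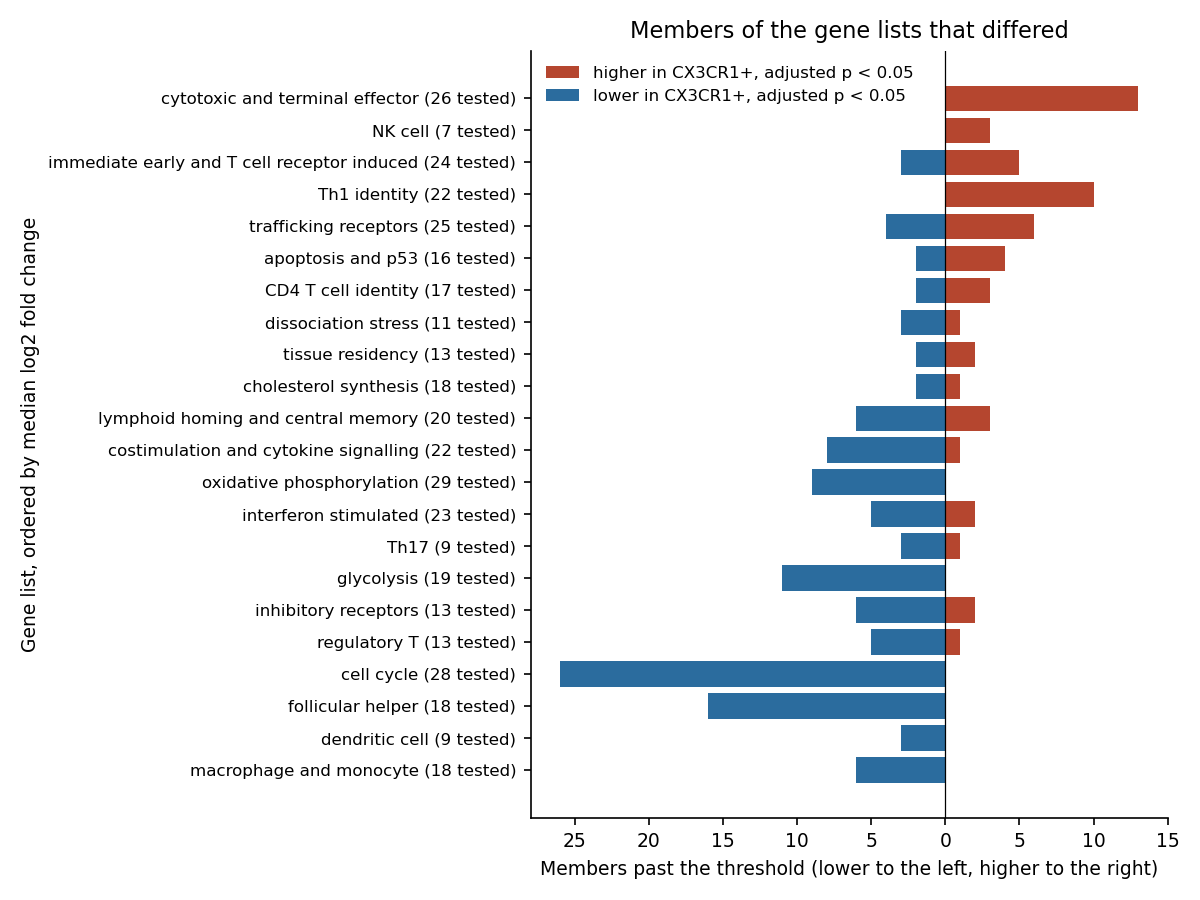
Number of members past adjusted p 0.05 (horizontal axis, higher in CX3CR1+ to the right and lower to the left) in each gene list with at least 5 tested members, ordered by median log2 fold change. The cell cycle list has the longest bar, 26 of 28 members lower, and the cytotoxic list the longest to the right, 13 of 26 with the sorting receptor Cx3cr1 among them.

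Immediate early genes and genes induced by the T cell receptor went both ways. Of 24 members 5 were higher, 3 lower and 16 not past the threshold (5 and 3 adjusted over the list alone, median 0.70, camera adjusted p = 0.0823). Nr4a1, an orphan nuclear receptor induced by antigen, was higher at 2.01 (SE 0.413, adjusted p = 0.00582), while Egr2, a zinc finger factor, was lower at -2.12 (SE 0.279, adjusted p = 0.000830) and Myc, which drives growth, at -2.11 (SE 0.375, adjusted p = 0.00296). The list summed to 5246 and 4627 CPM in CXCR3+ replicates 1 and 4 and to 1426 and 1088 CPM in replicates 5 and 6, against 6421 ± 1916 CPM in CX3CR1+ cells. Replicates 5 and 6 of the CXCR3+ group also carried reads of Y-linked genes that were nearly absent from the other 6 libraries. Ddx3y had 1241 and 456 reads against at most 1 elsewhere, and Kdm5d 485 and 622 against at most 5. Xist had 38 and 27 reads in replicates 5 and 6 against at least 9335 elsewhere. The list passed without CXCR3 replicate 1 (adjusted p = 0.00741, 9 members higher), CXCR3 replicate 4 (0.0143) or CX3CR1 replicate P8-4 (0.029), without both libraries titled P8 (0.0168) or with a term for them (0.0224), and 3 members were higher without CX3CR1 replicate 1 or P8-2. The median was 0.45 without CXCR3 replicate 5 and 0.42 without replicate 6.

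Interferon-stimulated genes, stress genes and p53 targets showed no call as lists. Of 23 interferon-stimulated genes 2 were higher and 5 lower (2 and 6 adjusted over the list alone, median -0.44, camera adjusted p = 0.0661). Irf7, a transcription factor of the interferon response, was higher at 1.88 (SE 0.219, adjusted p = 0.000545) and Ifit1 and Ifi27l2a were both lower at -1.18. Of 11 genes induced by tissue dissociation 1 was higher and 3 lower (1 and 4 adjusted over the list alone, median -0.05, camera adjusted p = 0.169). Their sum was lower, at 4375 ± 1483 CPM against 7693 ± 1309 CPM without overlap of the groups (exact permutation p = 0.0286, 0.0638 after adjustment). The heat shock gene Hspd1 was lower at -1.50 (SE 0.189, adjusted p = 0.000731) and Hsp90ab1 at -0.69 (SE 0.155, adjusted p = 0.00892). Of 16 apoptosis and p53 genes 4 were higher and 2 lower (4 and 2 adjusted over the list alone, median 0.02, camera adjusted p = 0.752). Pmaip1, a death-promoting BH3 protein, was higher at 1.59 (SE 0.347, adjusted p = 0.00778), Sesn1, a p53 target, at 1.44, and Ccng1, another p53 target, was lower at -0.56. The interferon list passed without CX3CR1 replicate 4 (adjusted p = 0.00399, 12 members lower) or CXCR3 replicate 1 (0.0289), and had 2 lower without CX3CR1 replicate 1 or P8-2 or CXCR3 replicate 6, and 3 without P8-4. The interferon median was -0.67 without CX3CR1 replicate 4, -0.24 without P8-4 and -0.08 without both libraries titled P8. With each library left out in turn the median of the stress list ran from -0.51 to 0.05 and that of the p53 list from -0.13 to 0.07. Without CX3CR1 replicate 1 or P8-2, 2 apoptosis and p53 members were higher. The higher count of the interferon list was 1 without any library but CXCR3 replicate 4 or 6, the lower count of the p53 list 1 without any but CX3CR1 replicate 4 or CXCR3 replicate 5, and the higher count of the stress list 0 without any but CX3CR1 replicate 4 or CXCR3 replicate 4.

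Genes of CD4 T cell identity were balanced between the populations. Of 17 members 3 were higher, 2 lower and 12 not past the threshold (3 and 2 adjusted over the list alone, camera adjusted p = 0.962), and the median of -0.0392 and the mean of 0.00178 differed in sign. Their sum was 6586 ± 313 CPM against 6517 ± 734 CPM. Bcl11b, a transcription factor of T cell commitment, was higher at 0.42 (SE 0.101, adjusted p = 0.0122), a call lost without CX3CR1 replicate P8-2 (0.0548). The 3 higher members numbered 1 without CX3CR1 replicate 1 or 4 or CXCR3 replicate 4 or 6, and 0 without P8-2. The 2 lower numbered 1 without CX3CR1 replicate 4, 2 without CXCR3 replicate 6 and 0 without any other library. The median ran from -0.10 to 0.05 with each library left out.

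Transcripts typical of other cell types were rare in most libraries, apart from CXCR3+ replicate 6. Of 18 macrophage and monocyte genes 6 were lower in CX3CR1+ cells and 0 higher (12 and 0 adjusted over the list alone, median -2.79, camera adjusted p = 0.0178, adjusted p = 0.678 with an estimated correlation). They summed to 1511 CPM in CXCR3+ replicate 6 and to between 132 and 285 CPM in the other 3 CXCR3+ libraries, against 157 ± 50.5 CPM in CX3CR1+ cells. Of 9 dendritic cell genes 3 were lower and 0 higher (3 and 0 adjusted over the list alone, median -2.57, camera adjusted p = 0.125), at 1100 CPM in replicate 6. Cd74, the class II invariant chain, was lower at -3.62 (SE 0.956, adjusted p = 0.0188), or at -1.85 (adjusted p = 0.0433) without replicate 6, and that call was lost without CX3CR1 replicate 1 (adjusted p = 0.0533) or P8-2 (0.0622) and stood at 0.05 without P8-4. Csf1r, the receptor for macrophage colony-stimulating factor, was lower at -3.94 (SE 1.26, adjusted p = 0.0417), and no longer called without CXCR3 replicate 6 (-1.61, adjusted p = 0.249) or CX3CR1 replicate 1 (0.106), 4 (0.0651), P8-2 (0.0987) or P8-4 (0.0963).

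Without CXCR3 replicate 6 the macrophage list did not pass (median -0.77, adjusted p = 0.120), with 0 of 18 members past the threshold in edgeR and 2 lower at an unadjusted p under 0.05, and 1 of 9 dendritic cell members was lower. The call of the macrophage list was also lost without CX3CR1 replicate 1 (0.0546), with a term for the libraries titled P8 (0.0639) or for Y-linked reads (0.768), with a replicate block (0.961), in the libraries numbered 1 and 4 with (0.984) or without a block (0.965), without CXCR3 replicates 5 and 6 together (0.682) and with fry (0.352). Its lower members numbered 0 without CX3CR1 replicate 1 or P8-2, 1 without P8-4, 9 without CX3CR1 replicate 4 or CXCR3 replicate 4 and 10 without CXCR3 replicate 1. In these settings 19 or 20 members were tested, against 18 with all libraries. The dendritic cell list passed without CX3CR1 replicate 4 (0.0203) or P8-2 (0.0385) or CXCR3 replicate 1 (0.0168) or 5 (0.0340) and in the libraries numbered 1 and 4 with a block (0.0295). Its median was furthest from 0 without CX3CR1 replicate 4 and was -0.97 without CXCR3 replicate 6. Lower dendritic members numbered 0 without CX3CR1 replicate 1, 1 without P8-2 or P8-4, 6 without CX3CR1 replicate 4 and 5 without CXCR3 replicate 1. Of this list 10 or 11 members were tested in these settings, against 9 with all libraries. Lists with fewer than 5 tested members gave 0 higher and 1 lower of 4 B cell genes (Cd22), 1 higher (Prdm1) and 2 lower (Jchain and Irf4) of 4 plasma cell genes, and 0 of 2 neutrophil genes. The same count was 1 higher of 2 CD8 and unconventional T cell genes (Cd163l1), 1 higher of 4 erythroid and platelet genes (Itga2b), and 1 lower stromal and endothelial gene, Pecam1 at -2.32 (SE 0.243, adjusted p = 0.000328). Of these calls, that of Jchain was lost without CX3CR1 replicate P8-2 (adjusted p = 0.0657), that of Cd22 without CX3CR1 replicate 1, 4 or P8-2 or CXCR3 replicate 6 (0.0518 to 0.116). Prdm1 lost its call without CX3CR1 replicate 1, 4 or P8-2 or CXCR3 replicate 1 or 5 (0.0539 to 0.0990), and Irf4 without CX3CR1 replicate 1, P8-2 or P8-4 or CXCR3 replicate 1 or 4 (0.0958 to 0.135). The call of Cd163l1 was lost without CX3CR1 replicate P8-2 or P8-4 or CXCR3 replicate 4, 5 or 6 (0.0655 to 0.123), and that of Itga2b without any library but CX3CR1 replicate 4 or CXCR3 replicate 5 (0.0608 to 0.101).

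**Figure D4:**
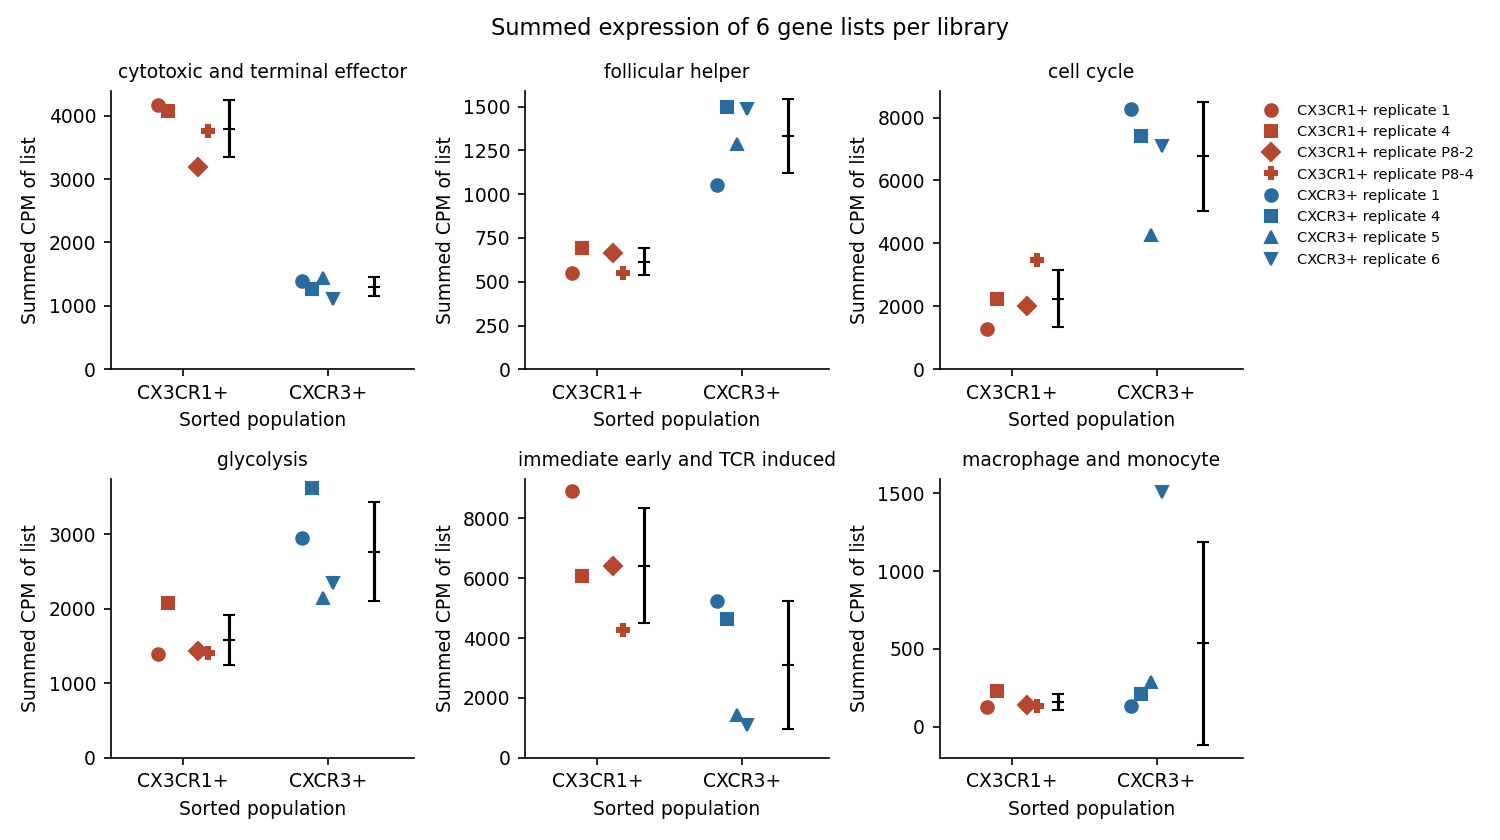
Summed CPM of 6 gene lists (vertical axis) in each of the 8 libraries by sorted population, with coloured points for libraries and black marks for the group mean ± SD (n = 4 per group). Cell cycle genes average 2244 CPM in CX3CR1+ and 6763 CPM in CXCR3+ libraries, and macrophage genes reach 1511 CPM in CXCR3+ replicate 6 alone.

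Over the 22 lists tested, 2 were higher and 6 lower by camera with its preset correlation of 0.01. With the correlation estimated from the data camera called 0 lists, with 2 at an unadjusted p under 0.05, and fry, which tests whether the members move on balance 1 way, called 10. An exact permutation test of the mean of each list put 11 of the 22 at the smallest p that 70 assignments allow, 0.0286 (0.0571 after adjustment over the lists), and none passed.

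Some further called members of lists with 5 or fewer calls in a direction are named here, in part after their values were seen. Higher were Klf3 and Lef1 of central memory, Ier2, Rel, Klf6 and Btg2 of the immediate early genes, Stat2 of the interferon genes, Itga1 of residency, Cd247 and Lck of CD4 identity, Bag3 of dissociation stress, and Mcl1 and Bbc3 of apoptosis. Lower were Tnfrsf18, Tnfrsf9 and Il2ra of the regulatory genes, Il17re of T helper 17, Irf4 of the immediate early genes, Oasl2, Ifi44 and Bst2 of the interferon genes, Cd44 and Itgb3 of trafficking, Litaf of residency, Srebf2 of cholesterol synthesis, Cd3g and Ubash3a of CD4 identity, and Hsp90aa1 of dissociation stress. The call of Lck was lost without any library but CXCR3 replicate 5 (adjusted p = 0.0664 to 0.111), that of Cd3g without any but CX3CR1 replicate 4 or CXCR3 replicate 6 (0.0595 to 0.0873). Srebf2 lost its call without any but CX3CR1 replicate P8-4 or CXCR3 replicate 4 (0.0719 to 0.117). Itga1 was lost without CX3CR1 replicate 4 or P8-2 or CXCR3 replicate 1 or 4 (0.0590 to 0.0862), and Hsp90aa1 without CX3CR1 replicate P8-2 or CXCR3 replicate 1 or 4 (0.0659 to 0.0836).

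The libraries titled P8 occurred among CX3CR1+ cells only, so that a difference tied to that title and a difference between the populations were partly inseparable. In the remaining libraries the title tags P11 and P9 follow the populations. A difference tied to these tags cannot be told apart from one between the populations in any setting. For the title P8, a term and removal were tried. With a term for P8, 809 genes were higher and 847 lower, and without the libraries titled P8 466 and 654. Within the 4 libraries numbered 1 and 4, 2 of each population, 624 genes were higher and 849 lower, or 956 and 1191 with those numbers as a replicate block. Without the 2 CXCR3+ libraries that carried Y-linked reads, 1089 were higher and 1265 lower. Of the single libraries, leaving out CX3CR1 replicate 1 or P8-2 reduced the count of higher genes by more than 1.5 times, to 888 and 817.

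Ribosomal RNA and nuclear RNA took different shares of the reads. Rn45s, the precursor of ribosomal RNA, held 16.5% ± 4.25 of counts in CX3CR1+ libraries and 30.6% ± 9.50 in CXCR3+ libraries (SD, n = 4 each), with an exact two-sided permutation p of 0.0286, the smallest possible, and 0.0857 after adjustment over 6 library properties. Malat1, a nuclear long noncoding RNA, held 3.97% ± 0.801 against 1.54% ± 0.200, with the same exact p and adjusted p. The share of the 10 most abundant genes was 24.2% ± 3.67 against 35.4% ± 9.41 (exact p = 0.0571), and that of ribosomal protein genes 1.64% ± 0.313 against 2.16% ± 0.238 (exact p = 0.0857). Total counts (exact p = 0.4) and the number of genes detected (exact p = 0.2) did not pass either. Spearman correlation across genes was 0.943 to 0.979 between libraries of the same population and 0.879 to 0.940 between populations, with genes not being independent replicates.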

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

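The tests of the macrophage and class II genes for expression in every CXCR3+ library and for the sex of the mice were chosen only after the values were seen, while the test without CXCR3 replicate 6 was fixed before that. In each group of 4 libraries, a library was set apart when its gap to the nearest of the others, as a share of the whole range, exceeded Dixon's 95% critical value. Among 246 groups of 4 values this held for 34 values, where chance gives about 1 in 20 (5%), and 14 of the 34 lay in CXCR3 replicate 6.

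Genes of macrophages and of class II antigen presentation stood far above the other libraries in CXCR3 replicate 6. The CPM values there were 70.6 for Cybb (others 0.893 to 7.81), 77.6 for C1qb (0.638 to 9.43), 130 for Csf1r (0.128 to 17.9), 474 for Cd74 (18.6 to 67.5), 135 for H2-Eb1 (2.42 to 18.3) and 192 for H2-Ab1 (2.42 to 27.4), with 1511 for the macrophage and monocyte list (132 to 285) and 1100 for the dendritic cell list (85.9 to 176). These list sums were not at 1 level in the CXCR3+ libraries. The median log2 fold change of the 9 called genes, -3.66 with all libraries, was -0.888 without CXCR3 replicates 5 and 6 (median SE of the single genes 0.914). The 9 genes were picked with all libraries, and these 2 had been seen to hold the highest sums of both lists. The fall of the median therefore does not test expression by the CXCR3+ T cells at the same level in every library. In CXCR3 replicate 1, Csf1r at 0.128 CPM, which is 1 read, lay below all CX3CR1+ libraries (0.990 to 4.35). There, Cybb, C1qb and H2-Ab1 (0.893, 0.638 and 2.42 CPM) lay inside the range of the CX3CR1+ libraries. So did the macrophage sum, at 132 CPM against 126 to 232 CPM. Cd74 and H2-Eb1 (18.6 and 2.42 CPM) lay above all CX3CR1+ libraries but replicate 4. A higher level in CXCR3 replicate 1 was thus not seen for Csf1r, Cybb, C1qb and H2-Ab1. That rests on 1 library and at most 19 reads per gene. A smaller expression in every library stays open for the genes as a set. None of the 9 genes (0) had all 4 CXCR3+ libraries above the 4 CX3CR1+ libraries, but 1 CX3CR1+ library is enough to break such a separation, as replicate 4 did for Cd74, where the other CX3CR1+ libraries held 3.63 to 9.58 CPM and all CXCR3+ libraries at least 18.6 CPM. RNA from other cells in replicate 6 alone is a candidate explanation. The cells were sorted on tetramer and receptors, but the purity of the sort is not given in the sources used here. Without that library the median of the 9 genes was -1.61 (median SE of the single genes 0.858), so that RNA from other cells cannot be told apart from a smaller difference outside replicate 6. The median of the whole macrophage list was -0.25 (adjusted p = 0.682) without replicates 5 and 6 and 0.13 (adjusted p = 0.965) in the libraries numbered 1 and 4 without a block. The sex of the mice, which the Y-linked reads of replicates 5 and 6 raise, stays open as well. With a term for those reads the median of the 9 genes was -0.904 (median SE of the single genes 0.974), but the term covers replicate 6, so that it does not separate sex from RNA of other cells. Replicate 5, with Y-linked reads as well, summed to 285 CPM of macrophage and 176 CPM of dendritic cell genes, against 1511 and 1100 CPM in replicate 6. A trait shared by both would by itself leave this gap, of 1 library each, without a source. No other biological difference was tested for these genes.

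Other values set apart in CXCR3 replicate 6, in CPM, were 59.5 for Aff3 (others 8.51 to 17.0), 481 for Rora (593 to 616), 15.9 for Cd22 (1.53 to 2.13), 182 for the stromal and endothelial list (74.0 to 87.2), 0.196 for Klri2 (all others 0) and 0.294 for Klra3 (all others 0). The last pair rests on 2 and 3 reads.

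In CXCR3 replicate 4 the values were 44.9 CPM for Gzmb (others 9.39 to 13.1), 83.0 CPM for Hist1h3h (2.48 to 10.3), 95.1 CPM for Tigit (41.3 to 50.4) and 756 CPM for the inhibitory receptor list (348 to 397). In CXCR3 replicate 5 they were 590 CPM for Il7r (others 242 to 293), 57.3 CPM for Irf7 (35.4 to 37.5), 10.7 CPM for Mvd (6.63 to 7.24), 517 CPM for Lck (461 to 466) and 7598 CPM for the trafficking receptor list (5564 to 5806). In CXCR3 replicate 1, Rn45s held 44.8% of counts (others 24.7% to 26.5%) and the 10 most abundant genes 49.5% (29.5% to 31.4%).

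In CX3CR1 replicate 4 the values were 175 CPM for Tcf7 (others 307 to 332), 9.41 CPM for H2-Eb1 (1.54 to 2.14), 0.705 CPM for Itga2b (4.91 to 5.70), 2082 CPM for the glycolysis list (1396 to 1430) and 232 CPM for the macrophage and monocyte list (126 to 138), with 29.7% of counts in the 10 most abundant genes (22.2% to 22.5%). In CX3CR1 replicate P8-4, Il1r1 reached 4.58 CPM (others 0 to 0.475) and the CD8 and unconventional T cell list 33.4 CPM (11.1 to 14.8). In CX3CR1 replicate P8-2 the erythroid and platelet list summed to 22.8 CPM (others 10.1 to 11.7).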

How the results depend on the processing

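The alternatives for reads of Y-linked genes, Rn45s, gene length, GC content and the libraries numbered 1 and 4 without a block were tests chosen only after the results were seen. Cx3cr1 and Cxcr3 were called in the same direction under every alternative that gave them a value (6.38 to 8.47 and -4.85 to -3.84). Of the 2777 called genes, at least 99.8% kept their sign in each alternative, and between 603 and 3232 genes were called. Depth limits what can be seen of rare transcripts, since 3 counts correspond to 0.238 to 0.383 CPM per library. Labels that do not pair libraries by mouse limit the design. With a replicate block over the title numbers on all 8 libraries, 1078 genes were higher and 1165 lower, but only 2 numbers are shared between the groups and nothing shows that they mark a mouse. The deviations of libraries that share number 1 or 4 correlated across genes at r = 0.170 and 0.113, against -0.182 to 0.121 for the other pairs between populations, and genes are not independent replicates.

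Counts moved by more than 1.5 times in some settings. With a term for the libraries titled P8 there were 809 higher and 847 lower genes, and without these libraries 466 and 654, with 4 lists higher (fewer libraries). A test against a fold of 1.5 gave 270 and 333, a threshold of 0.01 gave 628 and 660, both stricter by construction, and the libraries numbered 1 and 4 without a block gave 624 and 849 (fewer libraries). Without a count filter 16 lists were lower, some of them lists with too few members to test under the filter, with the median of all genes at 0.18 (log2). Camera with an estimated correlation called 0 lists higher and 0 lower, fry called 4 higher, and a term for Y-linked reads left 1 higher. With each library left out in turn, higher genes numbered 817 to 1355, lower genes 954 to 1387, higher lists 2 to 4 and lower lists 5 to 10. Except where stated, the cause was not tested.

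Reversals of direction were of small medians or uncalled genes, apart from the called macrophage list and Csf1r. The median of the apoptosis and p53 list (0.0159) became -0.00584 with RLE scaling, -0.0742 with quality weights, -0.117 without the libraries with Y-linked reads and -0.0774 with a term for them, and ran from -0.132 to 0.0716 with each library left out. That of the dissociation stress list (-0.0515) became 0.0577 without a filter and 0.0154 with the P8 term, and ran from -0.505 to 0.0508. For the CD4 T cell identity list (-0.0392) the values were 0.0283 with the block, 0.00918 with the block on the libraries numbered 1 and 4, 0.00381 on these without a block and 0.0155 with the length trend removed, and ran from -0.104 to 0.0473. Tissue residency (-0.176) became 0.0320, 0.0129 with the block on the libraries numbered 1 and 4, and 0.00141 with the P8 term, and cholesterol synthesis (-0.199) 0.0414 and 0.0223 with the blocks. The macrophage list (-2.79) became 0.137 with the block, 0.0934 with the block on the libraries numbered 1 and 4 and 0.127 on these without a block, settings in which CXCR3 replicate 6 has no weight or is absent. Csf1r likewise became 0.396, 0.761 and 0.105.

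Il7r (-0.172) became 0.116, 0.0966 and 0.0950 in those 3 settings, 0.0230 with quality weights, 0.0987 without the libraries with Y-linked reads and 0.138 with a term for them, and ran from -0.315 to 0.200. Bcl6 (-0.273) became 0.235, 0.216, 0.219, 0.170 and 0.209 in the settings with blocks, without a block and with Y-linked reads, in that order, and ran from -0.416 to 0.0266. Tcf7 (-0.337) became 0.281, 0.262, 0.235, 0.384 and 0.427 in the same order, and Cxcr6 (-0.176) 0.00141 with the P8 term. The cause was not tested for these genes and lists.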

Other observations

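The gene families, the tests of the cell cycle genes and those of the immediate early genes were chosen only after the results were seen, while the tests over splits of the libraries were fixed before that. The families were picked for their values and hold genes that move together, so no p-value is given for them. In some families every called member was lower in CX3CR1+ cells. Of 57 tested histone genes 50 were lower and 0 higher, with a median log2 fold change of -2.08, for example Hist1h1a, a linker histone, at -2.26. Of 37 proteasome subunits 23 were lower, such as Psmd1 at -0.93, and of 75 ribosomal protein genes 35, such as Rps20 at -0.88. Of 8 chaperonin subunits, which fold actin and tubulin, 7 were lower, such as Tcp1 at -0.83. Of 12 structural maintenance of chromosomes and condensin genes (symbols starting Smc with a number, or Ncap) 7 were lower, such as Ncapg2 at -2.12. Of 20 cytosolic aminoacyl-tRNA synthetases 9 were lower, such as Vars at -1.59. With 1 library left out the ribosomal protein genes numbered between 20 and 51, with 20 without CX3CR1 replicate P8-2, 23 without CXCR3 replicate 1, and 11 without both libraries titled P8, and the synthetases 6 without CX3CR1 replicate 1 or P8-2. Without both libraries titled P8, 39 histone genes, 12 proteasome subunits, 5 chaperonin subunits, 6 structural maintenance and condensin genes and 5 synthetases were lower.

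Other families had members that were higher in CX3CR1+ cells. Of 12 killer cell lectin-like receptor genes 9 were higher and 0 lower, with a median of 6.23, or 5.20 with genes at 0 in a group set to their bound, among them Klrd1, the CD94 receptor chain, at 5.41 (8.04 without CXCR3 replicate 5) and Klre1, at least 163-fold higher with 538 counts against 0. Of 11 clock genes 7 were higher and 1 lower, with Per1, a repressor of the circadian loop, at 2.22, Nr1d2 at 1.51 and Tef at 1.58. The higher clock genes numbered 4 without CX3CR1 replicate 1 or P8-2 or CXCR3 replicate 4, and 1 without both libraries titled P8. The lower gene, Hlf at -2.90, was not called without CXCR3 replicate 1 or CX3CR1 replicate P8-2. The labels do not give the time of day of the harvest. Of 6 nuclear long noncoding RNAs 4 were higher, Neat1 at 1.77, Malat1 at 1.13, Lincpint at 1.40 and Miat at 1.96, the last at 2.81 without CXCR3 replicate 4, and 2 of the 6 were higher without both libraries titled P8. Of 72 snoRNA and host genes 11 were higher, a share near that of all genes tested (1378 of 11028 higher), so the family does not stand out. The 11 became 4 without CX3CR1 replicate 1 or CXCR3 replicate 6, and 5 without CXCR3 replicate 4 or 5 or CX3CR1 replicate P8-2. They became 2 without both libraries titled P8 or without the 2 CXCR3+ libraries with Y-linked reads. Genes with a longer total exonic length were on average higher, with a median log2 fold change of -0.0765 in the shortest of 5 equal groups of genes and 0.11 in the longest. Of called genes, 154 were higher and 305 lower in the shortest group, against 453 and 245 in the longest.

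Splits of the libraries speak only in part to chance as the source of the number of called genes. Of the 35 splits of the 8 libraries into 4 and 4, only the real split (1) called as many, 2777 genes in edgeR, and each of the other 34 called 0, with 70 to 1450 genes at an unadjusted p under 0.05 against 4186 in the real split. For the 8 called gene lists chance cannot be excluded, since 16 of the 35 splits called as many and the highest of the others called 12. That split joined CX3CR1 replicates 1, P8-2 and P8-4 with CXCR3 replicate 1. Splits that keep 3 libraries of a population together still carry part of its difference, so they are not a pure measure of chance. A split with 2 libraries of each population on both sides reached 10.

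Cell cycle genes were lower in CX3CR1+ cells, 26 of 28. A few libraries as the whole source are argued against by 25 members lower without CXCR3 replicate 6, 27 without the 2 CXCR3+ libraries with Y-linked reads, and 26 without the libraries titled P8. The shares of reads in Rn45s and Malat1 also differed between the populations and stay open as a sign of RNA composition or quality. That 26 members were lower without Rn45s does not test this, since TMM scaling already offsets the share of a single abundant gene. No biological explanation was tested.

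The median of the immediate early list, 0.702 with all libraries, was 0.0368 without the 2 CXCR3+ libraries that carry Y-linked reads. The low sums of this list in those libraries had been seen before they were left out, so the fall of the median does not show that they are its source. Sex of the mice, handling before lysis and a separate batch cannot be told apart here, since all are tied to the same 2 libraries. Nr4a1 was at 1.45 (adjusted p = 0.0218) without them. Xist and Y-linked reads differ in these 2 libraries, so that the 8 libraries were not 4 matched pairs of the same mice.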
